A study of Mus musculus with 20 samples.

How the data were processed

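DNA from the tails of 1 sire, 1 dam and 8 offspring, each labelled against DNA of the same reference male, was measured on 20 Agilent 2-colour arrays. Spot intensities were extracted by the authors with Feature Extraction 10.7.1.1, per the file headers, which also give the probe positions on mm9 (NCBI37). The processed signals are intensities that were background-subtracted, spatially detrended and linearly dye-normalised within each array, per the file headers, and the log ratio column is the log10 of red (Cy5) over green (Cy3) processed signal, per the file headers. Median spot and local background intensities were deposited as well. The deposited value table of the series holds log2 values of unstated making. Set against the scanner ratios they are log2 of reference over mouse on every array, with r of 0.962 or higher, slopes from 0.92 to 1.00 and column medians from -0.01 to 0.01; which further correction was applied stays unknown.

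Groups were taken from the sample labels, and the dye of each mouse from the labelled channels. The 2 arrays of a mouse were treated as a technical dye swap and averaged to 1 replicate; the labels say nothing of separate extractions. The number of mice and arrays limits the precision, with 1 sire, 1 dam and 8 offspring. Mice were paired on slides, the parents on slide 1 and offspring 1 and 2, 3 and 4, 5 and 6, 7 and 8 on slides 2 to 5, and arrays were scanned on 3 days. The quality report in the file headers read "evaluate" for slides 2 and 4 and "in range" for the others. Of 136470 features 6563 were control spots. The others were 129907 spots of 125877 probes of 45 to 60 bases, and at least 98.7% of them were well above background in both channels of each array, with 0 saturated.

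Log2 ratios of mouse over reference were computed from the processed signals, without the 117 to 258 spots per array carrying outlier flags. Spots of a probe were averaged and each array was centred on its autosomal median. Probes were split into islands at gaps over 50 kb. The mean of both orientations was segmented by optimal partitioning with a penalty of 2 times the noise variance times the natural log of the number of probes (Python 3.11.15, numpy 2.4.6, numba 0.67.0). A region was called at 5 or more probes, an absolute mean of at least 0.3, and the same sign with at least 0.1 in each orientation. Overlapping calls of the same sign were merged over mice, and each mouse was given a state at 0.25 with the same condition on orientations. Regions within 1 Mb of each other formed a locus. A background number of calls came from segmenting the difference between the orientations in the same way, without the condition on each orientation. Means at each locus were compared with 10000 windows of as many probes, at most 100, drawn from islands without a locus, which bears only on values too small to be called.

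Transmission was tested with an exact binomial test (scipy 1.17.1). Offspring were compared with 0, the reference, and with parents by limma 3.58.1 (R 4.3.3), using lmFit and eBayes with Benjamini-Hochberg adjustment. Regions to be named were fixed before the data were examined: of the offspring-only regions and of those with a state in a parent the 12 with the largest absolute ratio in their strongest mouse, of those with 1 state in all mice the 8 largest, of which 4 existed, and of each limma fit the 5 probes of smallest p per direction outside them.

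The calling was tested on simulated data, with steps implanted into the arrays of 2 offspring. Of 100 steps per size and length, 91 were recovered for gains of 0.4 over 5 probes and 98 or more for losses of 0.5 or 1, with 0 calls elsewhere. Calls elsewhere were counted only in islands that held no step and had no call before. Their number was thus nearly fixed in advance and is not a rate of false calls. Implanted steps were equal over probes. In simulated noise of each probe's spread, with 200 probes shifted by 0.3, the fit against the reference recovered 190 with 10 false calls, and the fit against parents 165 with 6. A shift of 0.1 was recovered at 99 probes against the reference and at 0 against parents. With no shift, both fits made 0 calls. The noise was drawn independently for each mouse and probe, so it held no error of the reference shared by all mice.

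Alternatives fixed before the data were examined covered thresholds of 0.2 and 0.5, minimums of 3 and 10 probes, a doubled penalty, gaps of 10 kb, normexp with an offset of 50, flagged spots kept, within-array loess, each orientation alone, the deposited value table, dim probes left out, each mouse left out and slide as a random block. Added after the data were seen were a running median over 9 probes, the family without slide 4, scan day as a block, and transmission without loci where a region had a state in both parents. For normexp the median spot intensities took the place of the mean intensities that had been planned. A correction for probe GC content and a test of gene groups in called regions were planned and not run, because probe sequences and an annotation of mm9 were not used here. The primary screen and copy number assays named in the design text were not analysed here.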

Results

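Tail DNA of 10 C57BL/6 mice of 1 family was compared with the DNA of a single reference male by 2-colour array comparative genomic hybridisation, in which mouse and reference DNA carry different dyes and compete for the same probes. The family held 1 sire, 1 dam and their 8 offspring. The series title places the family in a study of males exposed to continuous gamma rays at 1 mGy per day for 400 days, whereas the design text of the series calls this sire non-irradiated, so the exposure of the sire stayed unsettled here. The question of the series was whether offspring carry copy number differences that their parents lack. Each mouse was hybridised on 2 arrays with the dyes swapped, which gave 20 arrays on 5 slides, and the mean of the 2 orientations counted as 1 replicate. The array was a custom design for a secondary screen that packed probes around candidate loci of an earlier genome-wide screen, which was not analysed here. It carried 125826 autosomal probes, 48 X probes and 3 Y probes. Islands of 5 or more probes numbered 838 and covered 22246 kb, so the results describe those loci and not the genome at large. All positions below are on mm9 (NCBI37), and genes at the loci were not named because an annotation of that build was not used here.

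The dam carried about 1 more X dose than the reference male, and the sire did not. Ratios are log2 of mouse over reference, opposite in sign to the deposited value table. Over the X probes the median was 0.93 ± 0.04 in the dam and 0.00 ± 0.07 in the sire (mean and SD of 2 dye orientations of 1 mouse, as for all values per mouse below). Among offspring, whose sex the labels do not give, replicates 1 to 4 had X values of 0.01 ± 0.08, 0.00 ± 0.08, 0.08 ± 0.07 and 0.00 ± 0.03. Offspring 5 to 8 had X values of 0.87 ± 0.08, 0.77 ± 0.12, 0.93 ± 0.08 and 0.92 ± 0.06. Over the Y probes the dam was at -2.13 ± 0.03, and offspring 5 to 8 were at -1.44 ± 0.08, -1.13 ± 0.18, -2.40 ± 0.03 and -2.42 ± 0.06. Offspring 1 to 4 lay between -0.01 and 0.04 on Y, and the sire at -0.18 ± 0.20. Offspring 5 and 6, both on slide 4, had the Y values nearest to 0 among the mice with a raised X value. Only 3 Y probes stood behind each Y value, and their SD within the dam was 2.10.

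**Figure D1:**
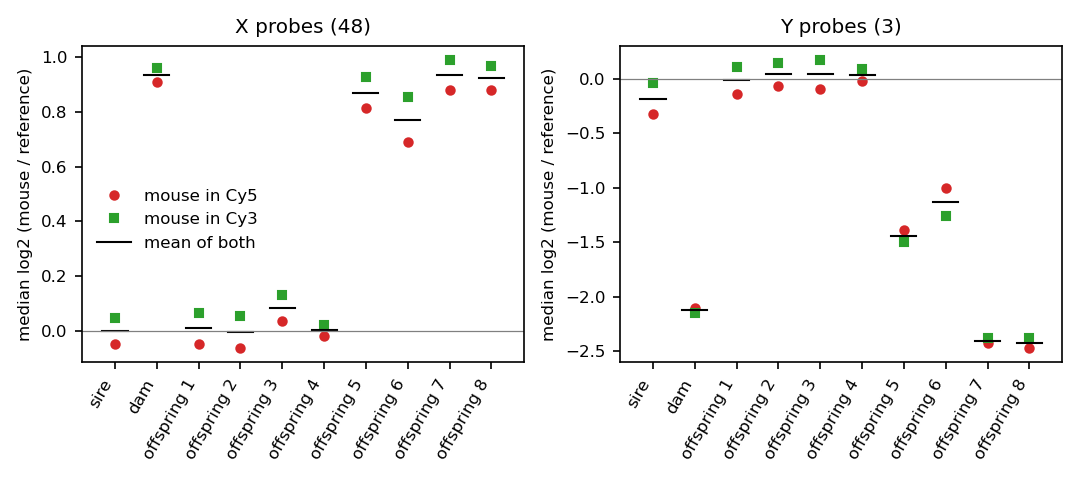
Median log2 ratio of mouse over reference over the X probes (left) and Y probes (right) of each of the 10 mice. Circles are arrays with the mouse in Cy5, squares those with the mouse in Cy3, and bars their mean; the bars of the dam and offspring 5 to 8 lie at 0.77 or higher on X and at -1.13 or lower on Y.

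Calling was limited by probe noise of 0.09 to 0.11 on single arrays and 0.04 to 0.06 on dye-swap means (robust SD of differences between neighbouring probes, log2). Across autosomal probes within a mouse, which are not independent replicates, the 2 orientations correlated at r between -0.42 in offspring 2 and 0.05 in offspring 6. Without the probes of called regions r was -0.47 to -0.06. A dye effect of a probe has opposite signs in the 2 orientations and cancels in their mean.

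Segmentation of each mouse gave 338 calls, of which 109 were gains and 229 losses. Offspring 6 had 110 calls and offspring 7 had 67, against 21 in the sire, 25 in the dam and 3 to 46 in the remaining offspring. The difference between dye orientations, which holds no copy number signal, gave 42 calls over the 10 mice, and 0 of them lay in a called region. These 42 were called without the condition on each orientation, so they are not a rate of false calls among the 338. Overlapping calls merged into 129 regions, 47 gains and 82 losses, at 14 loci separated by more than 1 Mb. Outside these loci lay 121929 of the 125826 autosomal probes, so few of the 42 background calls would be expected in a region by placement alone. Long loci were broken into many pieces, 38 regions at each of the loci on chromosome 4 at 101110298 and chromosome 7, so the number of regions is not a number of events. The number of calls was 567 at a threshold of 0.2 and 102 at 0.5.

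**Figure D2:**
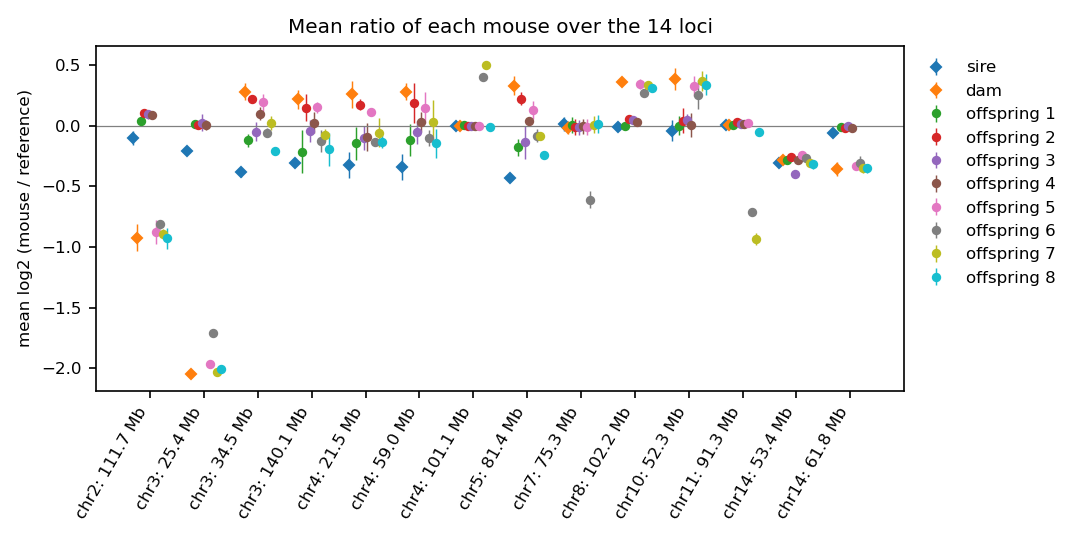
Mean log2 ratio of mouse over reference (y axis) of each mouse at the 14 loci (x axis, chromosome and mm9 start). Error bars are the SD over the 2 dye orientations; offspring 6 and 7 stand apart at the chromosome 4 locus that starts at 101110298 (0.40 and 0.50), and offspring 6 alone at chromosome 7 (-0.61).

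Offspring-only differences lay at 3 loci, and all 3 involved offspring 6. They made up 77 of the 129 regions, 38 of them in 1 offspring and 39 in more than 1. The largest was a gain on chromosome 4 from 101110298 to 101266418, 156 kb with 1079 probes from end to end. Its mean was 0.40 ± 0.02 in offspring 6 and 0.50 ± 0.03 in offspring 7, and the other 8 mice lay between -0.01 and 0.00 with an SD between mice of 0.00. Both values lay below 0.58, the log2 ratio of 3 copies over 2. The X value of the dam, 0.93 ± 0.04, also lay below 1, the log2 ratio of 2 copies over 1. A number of copies was therefore not read from these values. The gain ran to the last probe of its island, and the next probe was 489544 bp away, so its right end was not measured.

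A loss on chromosome 7 from 75324933 to 75443756 was present in offspring 6 and in no other mouse. It spanned 119 kb and 993 probes, with a mean of -0.61 ± 0.07 over the 274 called probes and a median of -0.52 over all probes. The other 9 mice had means between -0.02 and 0.01. Both ends lay inside the tiled island, and the 13 probes to its left averaged -0.01 in offspring 6. A single copy in place of 2 would give -1, and why the loss fell short of this was not tested.

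A short loss on chromosome 11 from 91290086 to 91290729, 644 bp with 11 probes, was shared by offspring 6 and 7. Its mean was -0.71 ± 0.01 in offspring 6 and -0.94 ± 0.05 in offspring 7. The other 8 mice lay between -0.05 and 0.03. The sire and the dam were at 0.01 ± 0.02 and 0.00 ± 0.02.

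**Figure D3:**
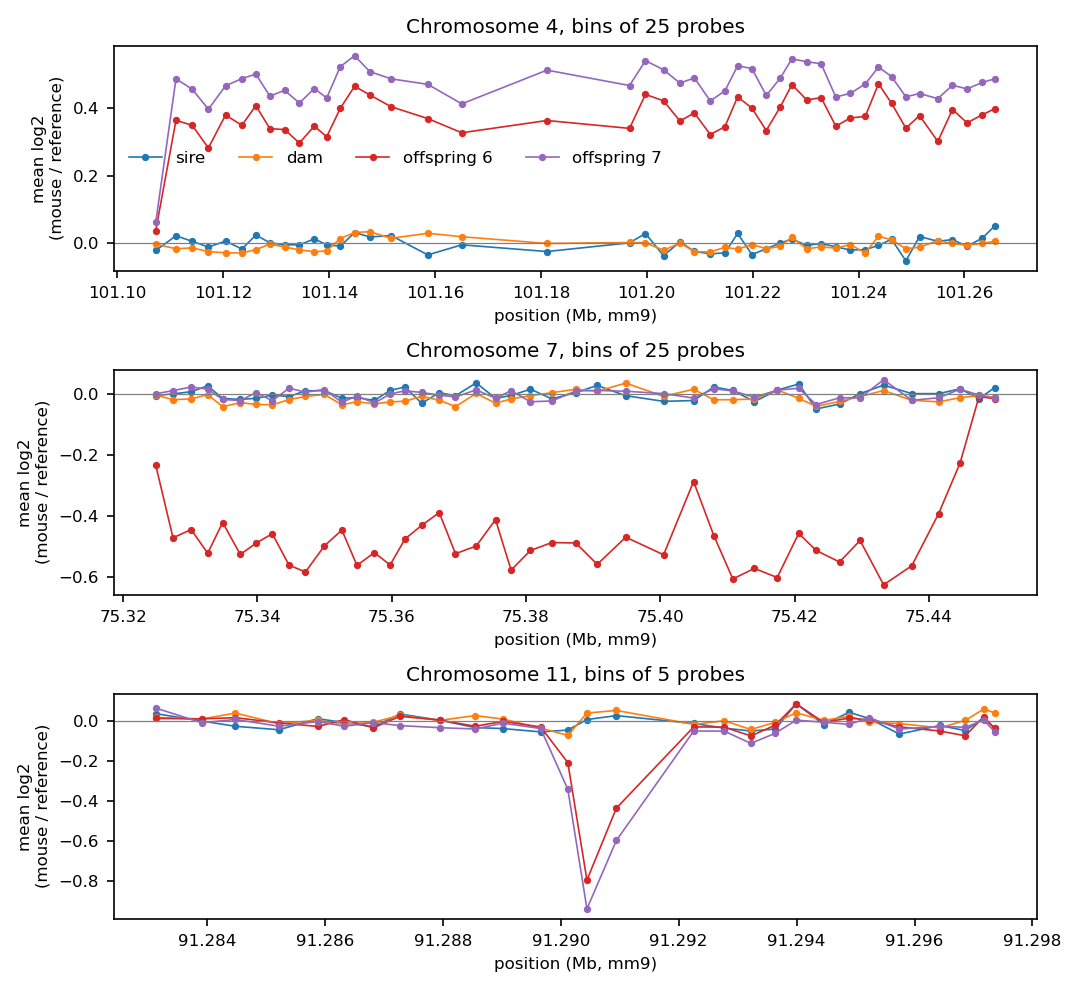
Mean log2 ratio of mouse over reference in bins of 25 probes (chromosomes 4 and 7) or 5 probes (chromosome 11) against mm9 position in Mb, for the sire, the dam and offspring 6 and 7. Offspring 6 and 7 rise over the chromosome 4 island and dip at chromosome 11, while offspring 6 alone is low over chromosome 7 and both parents stay near 0 in all 3 panels.

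By the naming rule the 12 offspring-only regions with the largest ratio were the chromosome 11 loss and 11 pieces of the chromosome 7 loss. Those 11 pieces held 5 to 10 probes each, with means in offspring 6 from -0.86 to -0.75. The strongest ran from 75347694 to 75348108, and the next from 75438012 to 75439125, 75443473 to 75443756, 75343277 to 75343931 and 75332634 to 75333277. The remaining 6 ran from 75383151 to 75384002, 75345741 to 75346161, 75415521 to 75415849, 75386753 to 75387132, 75441686 to 75441991 and 75439211 to 75439477.

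States shared with a parent were carried at 5 loci by the dam and by offspring 5 to 8, with no state in the sire or in offspring 1 to 4. At 2 of the 5 loci, the ratio was a gain, and at 3 a loss. The deepest loss, on chromosome 3 from 25424059 to 25453497, had a mean of -2.05 ± 0.01 in the dam and -1.97 ± 0.01, -1.71 ± 0.01, -2.03 ± 0.02 and -2.01 ± 0.00 in offspring 5 to 8. The 20 probes to its left averaged -2.05 in the dam, so it extended past the called probes within its island, which ran from 25410890 to 25456050. The sire lay at -0.21 ± 0.02 there, and offspring 1 to 4 between 0.00 and 0.03. A loss of 6 probes on chromosome 2 from 111694136 to 111694677 had means of -0.92 ± 0.11 in the dam and -0.93 to -0.81 in offspring 5 to 8. The sire lay at -0.10 ± 0.06 there.

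Smaller ratios of the same mice were found on chromosomes 8, 10 and 14. The chromosome 14 loss from 61809255 to 61822211 had a mean of -0.36 ± 0.06 in the dam and -0.35 to -0.31 in offspring 5 to 8. A gain on chromosome 8 from 102185507 to 102205238 had a mean of 0.36 ± 0.00 in the dam and 0.27 to 0.34 in offspring 5 to 8. On chromosome 10, from 52261676 to 52264952, the gain was 0.38 ± 0.09 in the dam and 0.25 to 0.37 in the same offspring, with offspring 6 at 0.25 ± 0.12, at the state threshold. The mice with these 5 states were those with X values of 0.77 or higher. Slides 4 and 5 held offspring 5 to 8 and no other mice, and slides 2 and 3 held offspring 1 to 4, so slide and state could not be told apart among offspring. The sire and the dam shared slide 1 and differed at all 5 loci, these being the loci with a state in the dam and none in the sire.

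Counted over the 6 loci with a state in exactly 1 parent, 19 of 48 offspring states matched the parent, 39.6%. Set against 1 in 2, the p was 0.193 (exact binomial test, two-sided), a test that takes the 48 states as independent. They were not, because 5 of the 6 loci were carried by the same 4 offspring, or by 3 of them at chromosome 10, so the p says little about transmission. The same holds for 5 alternatives that let more loci in and passed the test, from 17.7% at a threshold of 0.2 to 36.4% with mice in Cy5 alone. At the chromosome 3 locus from 140075589 to 140076501 the state was in the sire, and 0 of 8 offspring matched it. A second region there, of 6 probes from 140075849, had a state in both parents, -0.32 in the sire and 0.30 in the dam, and without this locus 19 of 40 states matched, 47.5%. The chromosome 10 region tested was matched by 3 offspring, and 4 offspring matched at each of the remaining 4 loci.

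Opposite ratios in the parents marked 5 short loci of 5 to 9 probes. They began on chromosome 3 at 34506482 and 140075589, on chromosome 4 at 21525287 and 59035680, and on chromosome 5 at 81444285. The sire lay between -0.43 and -0.31 at all 5, and the dam between 0.22 and 0.33. Offspring 2 and 5 were above 0 at all 5 loci, at 0.15 to 0.22 and 0.11 to 0.19. Offspring 1, 3, 6 and 8 were below 0 at all 5, and offspring 8 reached -0.24. No offspring passed the state threshold of 0.25 at any of these loci.

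The family as a whole was low over a long stretch of chromosome 14, from 53387742 to 54327239, 939 kb with 1118 called probes in 29 regions. Means were -0.31 ± 0.04 in the sire, -0.28 ± 0.03 in the dam and -0.40 to -0.24 in the offspring. The lowest value, -0.40 ± 0.03, was that of offspring 3, and the highest, -0.24 ± 0.03 in offspring 5, fell just short of the state threshold. Of the 129 merged regions 4 had the same state in all 10 mice, and all 4 lay in this stretch. They ran from 54078453 to 54079111 (mean over 10 mice -0.34, SD 0.03), 53387742 to 53759004 (-0.33, SD 0.05), 53965317 to 53966011 (-0.31, SD 0.04) and 53987091 to 53991232 (-0.30, SD 0.06). All mice were measured against 1 reference, so a difference of the reference itself would appear in every mouse.

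**Figure D4:**
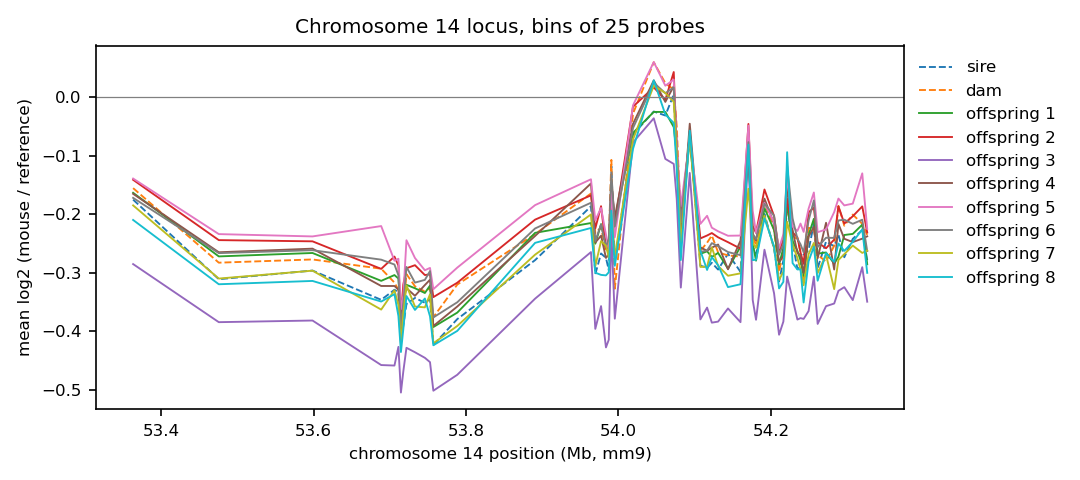
Mean log2 ratio of mouse over reference in bins of 25 probes against position on chromosome 14 (Mb, mm9) for each of the 10 mice, parents dashed. All mice lie below 0 over most of the stretch, with a return towards 0 in the middle, and offspring 3 is lowest, with a median over bins of -0.37.

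Among the 52 regions with a state in a parent, the 12 with the largest ratio included 3 of the chromosome 3 loss, from 25426956 to 25430072 (-2.14 in the dam), 25447100 to 25453497 and 25424059 to 25425564, and the chromosome 2 loss. Another 4 lay in the long chromosome 14 stretch, strongest in offspring 3. Of these, 2 had the same state in all mice, and the others ran from 54304362 to 54314573 (-0.50) and 54252996 to 54253977 (-0.48). The last 4 were on chromosome 14 from 61820469 to 61820852 (-0.59 in offspring 8), chromosome 10 from 52264258 to 52264952 (0.45 in offspring 7), chromosome 8 from 102204664 to 102205238 (0.43 in offspring 7) and chromosome 5 from 81444285 to 81444678 (-0.43 in the sire).

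Offspring differed from the reference mouse at many single probes, mostly by little. Of 125826 autosomal probes, 10744 were higher and 11741 lower (limma, Benjamini-Hochberg adjusted p below 0.05, n = 8), and 749 of them had an absolute mean of at least 0.3. The long chromosome 14 stretch held 1178 of the lower probes among its 1399. Outside the 14 loci 21076 probes passed, with a median absolute difference of 0.06, and 127 of these reached 0.3. This test leaves out the spread of the single reference mouse. The number of probes past the test, 22485, was 14916 with normexp, 14387 without offspring 1, 13364 without offspring 4 and 13715 without offspring 7.

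The 5 higher probes of smallest p outside the named regions were A_67_P07712575 on chromosome 12 at 95868420, A_67_P17855375 on chromosome 12 at 48144505, A_67_P05310224 on chromosome 4 at 88320658, A_67_P05572007 on chromosome 5 at 53193549 and A_67_P04351562 on chromosome 1 at 172243191. The first had a mean of 0.58 (SE 0.01, limma adjusted p = 9.27e-08) and ranged from 0.52 to 0.62 over 8 of 8 offspring. Means of the other 4 were 0.32, 0.25, 0.13 and 0.24. The 5 lower probes were A_67_P08113870, A_67_P19023393, A_67_P19024323, A_67_P19023429 and A_67_P19024377, all in the long chromosome 14 stretch between 53994847 and 54296879, with means of -0.55, -0.50, -0.38, -0.57 and -0.40.

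Offspring did not differ from their parents at any autosomal probe that passed the test (limma, 8 offspring and 2 parents, 0 of 125823 probes at an adjusted p below 0.05, 4183 at an unadjusted p below 0.05). With scan day as a block, 1 probe passed, A_67_P01337642 on chromosome 6 at 56900137, higher in offspring by 0.54 (limma adjusted p = 0.0286). Within the first scan day, which held both parents and 2 offspring, 0 passed by limma and 3839 had an unadjusted p below 0.05. Both unadjusted numbers, 4183 and 3839, were below a share of 0.05 of the probes tested, the share expected with no difference. Without the dam 10 probes passed, in a fit whose parent arm was the sire alone, assumed to vary like the offspring. The probes of smallest p higher in offspring were A_67_P01444057 on chromosome 6 (0.18, SE 0.03), A_67_P19254614 on chromosome 14 (0.20), A_67_P10102388 on chromosome 1 (0.19), A_67_P15809409 on chromosome 8 (0.12) and A_67_P00209001 on chromosome 1 (0.63). Those lower in offspring were A_67_P01147573 on chromosome 5 (-0.35, SE 0.05, limma adjusted p = 0.869), A_67_P11644902 on chromosome 2 (-0.26), A_67_P14468979 on chromosome 6 (-0.16), A_67_P17409458 on chromosome 11 (-0.18) and A_67_P16721547 on chromosome 10 (-0.23). A difference carried by 1 or 2 offspring, such as the chromosome 4 gain, is not what this comparison of means detects.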

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

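All tests of explanations in this part were chosen after the results were seen. Of 21 measures examined over the 8 offspring, 1 had a single mouse far from the others. That was the chromosome 7 locus, where only offspring 6 had a state, so this outcome was set by the calling and a rate by chance does not apply. Offspring 6 lay at -0.61 there and the other 7 between -0.01 and 0.01. The gap was 0.956 of the whole range, and the highest value of offspring 6 over 5 other ways of computing the ratio was -0.56.

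Offspring 6 and 7 shared a gain on chromosome 4 and a loss on chromosome 11; DNA of offspring 6 in the sample of offspring 7 would have carried the chromosome 7 loss along, whereas offspring 7 lay at 0.0059 ± 0.07 there. DNA of offspring 7 in the sample of offspring 6 is argued against for the chromosome 11 loss, which needs a share of 82.2%, so that the chromosome 7 median of offspring 6 (-0.51 ± 0.07 over all probes) would lie at -0.28 or above. The difference from that bound was -0.232 (SD 0.0846 over orientations and resampled probes). For the chromosome 4 gain, at a share of 74.6%, the difference was -0.0904 (SD 0.166) and the mixture cannot be told apart, its spread being too large. Both shares take offspring 6 over offspring 7. Offspring 6 was nearer to 0 than the dam and offspring 5, 7 and 8 on X (0.77, against 0.87 to 0.93) and at the deep chromosome 3 loss (-1.71, against -2.05 to -1.97). The shares were not corrected for this. A slide effect is argued against by the slide-mates, offspring 5 and 8, whose value farthest from 0 at these loci was -0.0486. The parental value farthest from 0 was 0.0092. Both loci were chosen for having no state in a parent, so this value does not test a difference in the tail DNA of a parent. What else would give both changes in these offspring was not tested, and no biological explanation was tested.

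The dam and offspring 5 to 8 shared states at 5 loci on 5 chromosomes, which were all the loci with a state in the dam and none in the sire. Autosomal differences inherited from the dam would match between unlinked loci in about 1 of 2 cases, and all 32 of 32 comparisons of an offspring with its state at the chromosome 2 locus matched (exact binomial test, two-sided, p = 4.66e-10). These are states of locus means, with offspring 6 at the cut on chromosome 10 (0.25 ± 0.12); over the 216 ways of taking 1 region per locus, 28 to 32 matched (p at 28 of 1.93e-05). The sire shared the slide of the dam and had a state at 0 of the 5 loci. This was fixed by the choice of loci without a state in the sire, so it cannot decide on a slide effect. By locus means the mice with all 5 states were those with a raised X ratio, 10 of 10 mice sorted alike. By 1 region per locus 7 to 10 were sorted alike, counts that rest on the state threshold of 0.25. By value, in 17 of 17 regions every mouse with a raised X ratio lay farther in the direction of the region than every other mouse. The 17 regions are pieces of the same 5 loci in the same 10 mice, and are not separate cases. Probes that also bind X or Y sequence stay open as an explanation, and probe sequences were not examined.

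The sire was low at the chromosome 3 locus (-0.21 ± 0.02), where mice with a raised X ratio lay between -2.05 and -1.71. DNA of the dam in the sample of the sire would have raised X to 0.22 at the share of 17.8% that the chromosome 3 value needs, and X of the sire was 0.00055 ± 0.07. Probe noise is argued against by 0 of 10000 windows as far from 0 in the sire, and a slide effect cannot be told apart, because slide 1 held 0 other mice with a low X ratio. In both orientations the sire was also below all of offspring 1 to 4 on the 3 Y probes (-0.18 ± 0.20, against -0.01 to 0.04), on chromosome 2 (-0.10 ± 0.06, against 0.04 to 0.10), at the chromosome 14 loss (-0.06 ± 0.03, against -0.02 to 0.00) and at the chromosome 10 gain (-0.04 ± 0.09, against 0.00 to 0.04), and in 1 orientation at the chromosome 8 gain (-0.01 ± 0.01). A lower dose of Y sequence in the sire was not tested apart from its slide and stays open. A low value at a gain is not what it predicts, but the values at both gains lay within probe noise. Of 10000 windows, 1477 were as far from 0 as the sire at the chromosome 10 gain and 5614 at the chromosome 8 gain. The counts were 232 on chromosome 2 and 97 at the chromosome 14 loss.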

How the results depend on the processing

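The alternatives with a running median over 9 probes, without slide 4, with scan day, and with a transmission locus left out (47.5%) were chosen after seeing the data. Over 240 comparisons of a locus value of a mouse with a state, under 5 ways of computing the ratio, 0 changed sign, 206 moved by less than the SD over orientations and 34 by more. In 8 of them a value fell under the state threshold of 0.25, 7 with normexp and 1 with loess. With normexp these were the sire on chromosome 3 at 140075589 (-0.24) and on chromosome 4 at 59035680 (-0.24), the dam on chromosome 4 at 21525287 and 59035680 (both 0.23), offspring 6 on chromosomes 8 (0.25) and 10 (0.24), and offspring 2 on the long chromosome 14 stretch (-0.24). With loess it was the sire on chromosome 3 again (-0.25), the only state of the sire alone in the transmission test. Single orientations were left out of these comparisons, because the calling rule and the SD fix their outcome. A change of sign was unlikely in the others too, because every value compared had passed 0.25 with both orientations on the same side. Keeping flagged spots and leaving out dim probes changed few spots. The 3 offspring-only loci were found under every alternative of calling with all mice. Counts of calls (338) became 567 at a threshold of 0.2, 102 at 0.5, 535 with 3 probes, 192 with 10 probes, 194 with the doubled penalty and 218 without slide 4. Regions shared by all mice (4) became 1 at 0.2, 2 with 10 probes and 8 with the running median. Offspring-only regions (77) became 158 with 3 probes, 34 with 10 probes, 51 with mice in Cy3 alone and 41 without slide 4, which removes offspring 6. Transmission fell below 1 in 2 by the test at 17.7% with a threshold of 0.2, 20.8% with 3 probes, 26.4% with the doubled penalty, 36.4% with mice in Cy5 alone and 28.0% with mice in Cy3 alone, where 12, 18, 9, 46 and 25 loci entered in place of 6. Probes differing from the reference (22485) became 14916 with normexp; leaving out 1 mouse gave 13364 to 26378, the low values being 14387 without offspring 1, 13364 without offspring 4 and 13715 without offspring 7. Probes differing from parents (0) became 10 without the dam, where the lone sire was assumed to vary like the offspring, 0 without the sire or any offspring, and 1 with scan day as a block. The X value of the dam became 0.85 with normexp. The cause of these changes was not tested, except where fewer mice or probes entered. No paired analysis was possible because all 8 offspring had the same 1 sire and 1 dam. The GC correction and the gene group test, with its 10 kb alternative, were not run. Signal over background limited few spots, and ratios on slide 4 were closer to 0 on Y. Among the mice with a raised X ratio, offspring 6 was also nearest to 0 on X and at the 5 loci shared with the dam.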

Other observations

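Offspring 3 stood lowest over the long chromosome 14 stretch, at -0.40 ± 0.03, with 46 calls that all lay there, whereas the other offspring lay between -0.32 and -0.24. The highest value was that of offspring 5. The order of offspring was similar at the 5 short loci with opposite parents, although these lie on 3 chromosomes: offspring 2 lay between 0.15 and 0.22 at all 5, and offspring 8 between -0.24 and -0.13. Offspring 4 was above 0 at 4 of them and offspring 7 at 2. No test was run on either pattern.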
